A study of Oryza sativa with 25 samples.

How the data were processed

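RNA from rice callus and organs was hybridized to 25 Affymetrix Rice Genome Arrays in 8 groups: growing callus, callus after 2, 4, 6 and 8 days on regeneration medium, root and shoot with 3 arrays each, and young leaf with 4. Per the labels' protocols, callus was raised from seeds for 3 weeks at 30 °C and then moved to regeneration medium. Young leaf and root came from a greenhouse, and shoot came from plants kept for 4 weeks in a growth chamber, so organ and growth place differ together for shoot. The labels give a leaf number of 4 for young leaf and root and an age for shoot. Plant stage is thus stated on different terms and may differ as well. Biotinylated cRNA was made from 500 ng of total RNA, per the labels' protocols. The labels state that replicate 2 of growing callus, of 2 days and of 4 days carries an excess of poly(A) control RNA.

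The deposited values are linear intensity values, 1 per probe set and array, with no value missing and none at or below 0. GCOS 1.3 is named in the submitters' processing notes, and the summary, background and detection steps are not stated there. In the deposited intensity table the 75th percentile over the 57381 probe sets was 1 in each array. The number of arrays per group, not a read depth, limits the precision.

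From these values, 0.0274 (1 part in 10 of the median of all values, 0.274) was added and the log2 taken. A pseudocount of 50% of the median, called the larger pseudocount, moved 54 of 317 values of named genes by over 1.5 times. Detection calls were not used here, so a log2 change against a level under the median of the arrays depends on the pseudocount, and the order of such changes carries no information. Array medians ran from 0.220 to 0.355, a ratio of 1.61 that passed a preset limit of 1.5, so the log2 values were quantile normalized. The 187 control probe sets were left out, and 37212 of the other 57194 were tested because they lay above the array median in at least 3 arrays. The probe annotation assigned 1 gene to 22436 probe sets, several genes to 95 and none to 34663. All 17905 genes of the single-gene probe sets were found in the RefSeq gene table, but only 2431 carried a name other than a locus number. The tested probe sets covered 16836 genes, 2322 of them named. Probe sets whose identifiers end in _s_at or _x_at can detect related transcripts, which applies to Os8N3, ML, CPDK2, NSHB1, AMY3E, OsTIFY11b, LTP2-B, OsrbcS, OSH1, OsRR4, RCABP69, OsYAB1, OspolD1 and OsChia1c among the genes named.

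All arrays entered 1 limma fit (version 3.58.1, R 4.3.3) with a mean per group, 17 residual degrees of freedom and 5.40 prior degrees of freedom. A probe set was called where its Benjamini-Hochberg adjusted p lay under 0.05 within the comparison and its fold was at least 2; the change per day, a linear contrast over 2, 4, 6 and 8 days, had to reach that fold over 6 days. Each of the 4 callus times was compared with growing callus, the organs were compared in pairs, and growing callus was compared with the mean of the 3 organs. No array measured callus kept off regeneration medium for the same days. Against growing callus, the medium, the transfer and the culture age therefore change together and cannot be told apart. Named genes were the 5 largest rises and falls (3 for 2, 4 and 6 days and for shoot against root) among called, named, single-gene probe sets whose compared arrays did not overlap, together with the list members of smallest adjusted p.

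Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene and Benjamini-Hochberg adjustment over lists within each comparison, and again with an estimated correlation. The groups, comparisons, thresholds, list themes and alternative settings were fixed before the data were examined. The lists had been written as patterns on gene descriptions. The reference holds no descriptions, so symbol and synonym patterns for the same themes replaced them before any expression test, and some lists are small as a result. They cover photosystems and light harvesting, carbon fixation, chlorophyll synthesis, cytosolic ribosome, DNA replication, mitosis, cytokinin, auxin, organ patterning regulators, seed storage and late embryogenesis, class III peroxidases, glutathione S-transferases, expansins, secondary wall and lignin, mineral transport, aquaporins, pathogenesis-related proteins, heat shock proteins, labdane diterpenoid phytoalexins, jasmonate, low-oxygen enzymes, starch, the circadian clock, shoot and root regulators, and root markers. The last 2 lists had been written as loci, and they too were matched by symbol or synonym. A plastid ribosome list matched 0 genes and a core histone list 2, and neither was tested. Of 225 list tests, 82 were called at the preset correlation and 5 with an estimated correlation. Probe sets at least 4-fold higher in young leaf than root, or in root than young leaf, formed 2 organ-biased sets.

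Tested on simulated data with known changes among 37212 probe sets, the 8 day comparison recovered 97.0% of log2 changes of 1.5, 98.5% of changes of 2 and 100% of changes of 3, with 1 false call. Young leaf against root and the change per day recovered the same shares, with 6 and 0 false calls. Each share is of 67, 67 or 66 seeded probe sets, in the order of the sizes. The noise had the same spread in every group, so genes whose spread differs between groups were not covered. Same-numbered replicates were checked for shared deviations. Only for 4 days and growing callus did all 3 pairs pass a correlation of 0.1 (0.125 to 0.209), which by the preset rule pairs those arrays. The labels state no pairing. With the replicate number as a block over all groups, organs included, that comparison gave 1950 called probe sets against 1952. With growing callus, the mean same-number correlations were 0.044 for 2 days, -0.097 for 6 days and 0.052 for 8 days. Among the times on regeneration medium the mean was 0.109, against -0.055 for different numbers, so pairing there is not excluded. Mean same-number correlations were -0.069 for leaf and root, -0.014 for shoot and root and -0.042 for shoot and leaf. That block therefore does not model the pairing of the 4 day and growing callus arrays alone, whose effect was not tested. The 4 day results below ignore that pairing. Alternatives covered the pseudocount, filter, normalization, variance model, arrays in the fit, replicate block, poly(A)-excess arrays, left-out replicates and fold threshold.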

Results

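The arrays measured transcript levels in rice callus before and during regeneration and in 3 vegetative organs, which the series describes as references for reproductive samples. Levels below are deposited intensities, in which the 75th percentile of an array is 1, with the SD over 3 arrays (4 for young leaf), and log2 changes come from the fit across all arrays. Between replicates the correlation across probe sets ran from 0.964 to 0.989. The leading principal components carried 50.8% and 23.3% of the variance. Adjusted p-values are limma's. List results give camera's adjusted p over the lists.

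After 2 days on regeneration medium, 7 of 28 cytokinin genes stood higher than in growing callus, and the list as a whole was not called (adjusted p = 0.067). OsRR6, a type-A response regulator, rose from 0.960 ± 0.463 to 8.68 ± 1.77, and OsCKX5, a cytokinin-degrading dehydrogenase, rose from 0.286 ± 0.0828 to 3.18 ± 0.325 (SD, n = 3 each). The nonsymbiotic hemoglobins NSHB1 and NSHB2 fell by 1.48 and 1.56 on the log2 scale. The sucrose transporter gene Os8N3 (LOC4346153) fell from 3.24 ± 1.15 to 0.203 ± 0.123. The stress-inducible PBZ1 (LOC4352491) rose from 4.00 ± 1.82 to 47.7 ± 6.95.

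At 2 days, 1520 probe sets were called, 614 higher and 906 lower. The balance depends on the fold threshold, since 2115 were higher and 2014 lower by adjusted p alone. Agglutinin (LOC4335068, log2 3.88, SE 0.668, adjusted p = 0.000459), PBZ1 (3.66) and OsGLU13 (LOC4340679, 3.55) were among the named genes that rose. Os8N3 (log2 -3.81), the beta-glucosidase family gene Os9bglu31 (LOC4347545, -3.73) and the dehydrin OsDhn1 (LOC4330265, -3.16) fell. Of 28 cytokinin genes, 7 rose and 0 fell, and 7 rose adjusted over the list alone. These included OsRR5 (log2 2.83) and OsCKX11 (1.88). Of 15 shoot and root regulators, 4 rose, and 4 also adjusted over the list alone. All were cytokinin genes: OsRR6, OsCKX5, OsRR4 (1.51) and OsRR9 (1.27). That list was called (adjusted p = 0.0324), and the call was lost without 2 day replicate 2 (0.0604) and with an estimated correlation (adjusted p = 0.416 with an estimated correlation).

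Cell cycle lists shifted upward at 2 days. Of 41 mitosis genes, 7 rose and 0 fell, with 7 rising adjusted over the list alone, among them the cyclin CYCB1-1 (log2 1.21) and the kinesin KIN12C (1.01); the list was called (adjusted p = 7.2e-05; adjusted p = 0.416 with an estimated correlation). KIN12C, whose fold lies at the threshold, lost its call in several alternatives. Of 29 DNA replication genes 0 were called over all probe sets and 0 adjusted over the list alone, although the list shifted by a median log2 of 0.31 (adjusted p = 0.00914; adjusted p = 0.783 with an estimated correlation) and OsMCM3 had a log2 change of 0.92. That list's call was lost without growing callus replicate 1 (0.0607) or 2 day replicate 2 (0.0604). Of 12 low-oxygen genes, 2 fell and 0 rose, and 3 fell adjusted over the list alone (adjusted p = 0.00287, and adjusted p = 0.059 with an estimated correlation). Of 44 secondary wall and lignin genes, 4 fell and 2 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.00287; adjusted p = 0.593 with an estimated correlation). The lignin gene OsCCR1 fell by 1.73 and OsCAD3 rose by 1.79. Of 83 mineral transport genes, 8 fell and 0 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.0324; adjusted p = 0.416 with an estimated correlation), among them the phosphate transporter OsPht1;1 (log2 -1.87) and OsNAAT1 (-1.65). Of 59 auxin genes 5 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.0324, and adjusted p = 0.416 with an estimated correlation). The calls of the mineral and auxin lists were lost without growing callus replicate 1 (0.0688 and 0.0607) or 2 day replicate 2 (0.0604 for both).

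At 4 days, OsYAB7, OsYAB2 and OsYAB3 of the YABBY transcription factor family, known for roles in lateral organs, had risen. OsYAB7 (LOC4330130) went from 0.188 ± 0.0693 in growing callus to 2.21 ± 0.433 and OsYAB2 rose by 2.75 on the log2 scale, or 2.07 with the larger pseudocount. Of 44 organ patterning regulators, 10 rose and 3 fell, the same counts adjusted over the list alone, with the growth-regulating factor OsGRF10 (log2 2.22) and OsYAB3 (2.45) among them. The list was called (adjusted p = 0.00738; adjusted p = 0.444 with an estimated correlation). The chitinase genes Cht10 (log2 -2.76), OsChia1c (-2.46) and OsChia1a (-2.65) fell.

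In all, 1952 probe sets were called at 4 days, 797 higher and 1155 lower, a balance that also turned by adjusted p alone (2928 higher, 2602 lower). OsGLU13 (log2 3.82), OsYAB7 (3.38) and OsPM19L1 (LOC4338635, 3.34) rose, and Os9bglu31 (-3.96), Os8N3 (-3.89) and the lectin gene ML (LOC4326471, -3.32) fell. Of 12 low-oxygen genes, 3 fell and 0 rose, with 3 falling adjusted over the list alone: NSHB1 (log2 -1.76), NSHB2 (-1.69) and the alcohol dehydrogenase Adh2 (-2.57). That call (adjusted p = 0.00103) also held at adjusted p = 0.0232 with an estimated correlation. Of 44 secondary wall genes 10 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.00103; adjusted p = 0.613 with an estimated correlation). Of 23 pathogenesis-related genes 5 fell and 2 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.0325, and adjusted p = 0.634 with an estimated correlation). Of 35 jasmonate genes 4 fell and 0 rose, or 4 and 1 adjusted over the list alone (adjusted p = 0.0325; adjusted p = 0.634 with an estimated correlation), including OsTIFY11c (log2 -1.80). Of 41 mitosis genes 1 rose, 1 adjusted over the list alone (adjusted p = 0.00738; adjusted p = 0.634 with an estimated correlation), a call lost without growing callus replicate 1 (0.0948). Of 15 shoot and root regulators 4 rose, 4 adjusted over the list alone (adjusted p = 0.0325, and adjusted p = 0.408 with an estimated correlation), a call lost without 4 day replicate 1 (0.0543).

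Leaving out growing callus replicate 3 ended the calls of the pathogenesis-related (0.0782) and jasmonate (0.0597) lists, as did leaving out 4 day replicate 1 (0.0696 and 0.0543); the former was also lost without growing callus replicate 1 (0.0719) and the latter without 4 day replicate 3 (0.0605).

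By 6 days, 7 of 11 photosystem genes had risen (adjusted p = 1.1e-06; adjusted p = 0.0583 with an estimated correlation). Plastocyanin PETE (LOC4339833) reached 5.33 ± 2.11 from 0.228 ± 0.105, and the light-harvesting gene CAB2R rose by 3.79 on the log2 scale, or 3.18 with the larger pseudocount. The water channel gene OsPIP1;2 rose by 3.42. Of the photosystem genes 0 fell, and 7 rose adjusted over the list alone. Of 24 aquaporin genes 10 rose and 0 fell, again 10 adjusted over the list alone (adjusted p = 1.2e-05; adjusted p = 0.0583 with an estimated correlation).

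At 6 days 2266 probe sets were called, 1379 higher and 887 lower. Agglutinin (log2 4.60), PETE (4.44) and the TCP family gene PCF7 (LOC4325137, 4.32) rose, and Os9bglu31 (-3.93), OsCCR1 (LOC4331085, -3.52) and ML (-3.35) fell. Agglutinin stood at log2 3.79 without 6 day replicate 1 and 5.72 without replicate 3, and ML at -2.59 without replicate 3. Of 26 expansin and xyloglucan genes 7 rose and 0 fell, with 7 adjusted over the list alone, among them OsEXPB8 (2.18) and OsEXPB7 (2.67). The list was called (adjusted p = 0.00328, and adjusted p = 0.287 with an estimated correlation). Of 44 organ patterning regulators 11 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.287 with an estimated correlation). Of 59 auxin genes 10 fell and 5 rose, the same adjusted over the list alone (adjusted p = 0.0191; adjusted p = 0.287 with an estimated correlation). Of 12 low-oxygen genes 4 fell, 4 adjusted over the list alone (adjusted p = 0.00236, and adjusted p = 0.0531 with an estimated correlation).

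At 8 days 8 of 11 photosystem and 12 of 24 aquaporin genes had risen (adjusted p = 2.3e-07 and 2.8e-05, and adjusted p = 0.0731 with an estimated correlation for both). PETE stood at 6.52 ± 0.496, against 145 ± 10.8 in young leaf, and the Rubisco small subunit gene OsrbcS at 2.30 ± 0.596 against 0.326 ± 0.0364 in growing callus and 88.0 ± 16.9 in young leaf. RAB16D (LOC4350451), an abscisic acid-responsive dehydrin, stood at 27.1 ± 22.2 against 0.309 ± 0.140, with 40.8, 1.52 and 39.2 in the 3 arrays at 8 days. The auxin-response repressor gene IAA9 (LOC4331061) fell from 17.5 ± 3.99 to 2.30 ± 0.241.

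**Figure D1:**
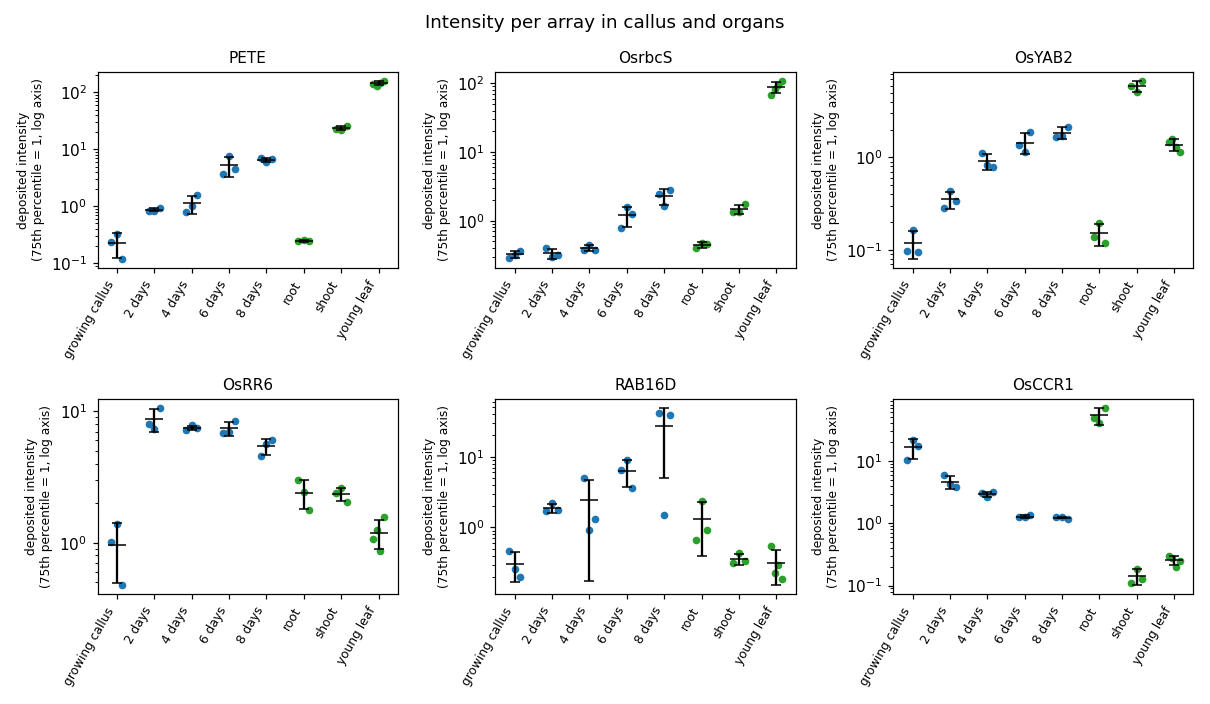
Deposited intensity (log axis, 75th percentile of an array equal to 1) of 6 genes in each array by group, with means as dashes and SD bars. PETE, OsrbcS and OsYAB2 were higher at 8 days than in growing callus, OsRR6 was higher at 2 days, 1 of the 3 RAB16D arrays at 8 days lay far below the others, and OsCCR1 was lower at 8 days.

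At 8 days 2922 probe sets were called, 1883 higher and 1039 lower, or 64.4% higher. Named genes that rose included Agglutinin (log2 6.67, SE 0.668, adjusted p = 2.1e-07), RAB16D (5.43, SE 0.835, adjusted p = 5.1e-05), the metallothionein OsMT-I-2b (LOC4326409, 5.17, SE 0.385), RAB16C (LOC4350452, 5.01, SE 1.09) and PETE (4.78, SE 0.256, adjusted p = 1.9e-11). Both RAB16 genes varied widely between the 8 day arrays, RAB16C standing at 19.2 ± 16. Their SE and adjusted p use 1 spread per probe set pooled over all 8 groups, so they do not measure the 8 day spread alone. Leaving out 8 day replicate 1, 2 or 3 gave log2 4.61, 7.01 or 4.67 for RAB16D and 4.09, 6.81 or 4.11 for RAB16C. OsMT-I-2b stood at 0.0924 in growing callus, under the median of the arrays, and its value was 4.21 with the larger pseudocount. Those that fell included OsCCR1 (log2 -3.59), Os9bglu31 (-3.50), the amylase and subtilisin inhibitor RASI (LOC4336455, -3.28), the chitinase-like Chib3H-a (LOC4351194, -2.95) and IAA9 (-2.79).

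Of 11 photosystem genes, 8 rose at 8 days and 0 fell, with 8 adjusted over the list alone. Of 3 carbon fixation genes 2 rose, 2 adjusted over the list alone: OsrbcS (log2 2.69) and the Rubisco activase gene OsrcaA1 (1.11), and that list was called (adjusted p = 0.0129; adjusted p = 0.146 with an estimated correlation). OsrcaA1 lost its call without 8 day replicate 1 (log2 0.81) or growing callus replicate 3 (0.97). Of 24 aquaporin genes 12 rose and 0 fell, and 13 rose adjusted over the list alone (adjusted p = 2.8e-05, and adjusted p = 0.0731 with an estimated correlation); OsPIP1;2 rose from 3.04 ± 0.118 to 35.4 ± 11 and OsPIP1;1 from 20.7 ± 2.48 to 43.1 ± 6.95. Of 26 expansin genes 8 rose, 8 adjusted over the list alone (adjusted p = 0.0314; adjusted p = 0.484 with an estimated correlation), including OsEXPB8 (log2 2.66). The expansin call was lost without growing callus replicate 2 (0.0937), 8 day replicate 1 (0.0781) or all 3 arrays with excess poly(A) controls (0.105). Of 30 heat shock genes 9 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0107; adjusted p = 0.391 with an estimated correlation), with the factor gene OsHsf-14 (log2 1.66) and the chaperone CLPB1 (1.93) among them.

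Of 59 auxin genes 14 fell and 5 rose at 8 days, the same adjusted over the list alone (adjusted p = 0.00187, and adjusted p = 0.15 with an estimated correlation). IAA26 (log2 -2.61), IAA12 (-2.63) and IAA4 (-1.86) were among those that fell. Of 12 low-oxygen genes 4 fell and 0 rose, 4 adjusted over the list alone (adjusted p = 0.0107; adjusted p = 0.0731 with an estimated correlation), with Adh2 at -2.72 and NSHB2 at -1.85. Of 29 DNA replication genes 1 fell, 1 adjusted over the list alone (ORC5, log2 -1.17), and the list shifted downward by a median of -0.43 (adjusted p = 0.000191; adjusted p = 0.484 with an estimated correlation). Of 23 cytosolic ribosome genes 0 were called and 0 adjusted over the list alone, while the list shifted by a median of -0.23 (adjusted p = 0.0229, and adjusted p = 0.77 with an estimated correlation); this was lost without 8 day replicate 1 (0.0781) or 3 (0.0534).

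Of 28 cytokinin genes 7 had risen and 1 fallen at 8 days, the same adjusted over the list alone, with LOGL7 at log2 2.50 and OsRR6 at 2.63; the list was not called (adjusted p = 0.117). Of 44 organ patterning regulators 9 rose and 4 fell, the same adjusted over the list alone, and the list was not called (adjusted p = 0.0787). OsYAB2 (log2 3.75, or 2.98 with the larger pseudocount) rose, and OsWOX6 (-1.83) and OsERF078 (-2.18) fell. Within the shoot and root regulator list, the knotted-like shoot meristem genes OSH1 (log2 1.13, adjusted p = 0.0144) and OSH71 (1.83) rose by 8 days, to 0.50 ± 0.152 for OSH1 against 6.69 ± 0.970 in shoot. The crown root regulator OsWOX11 had a log2 change of 0.30.

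Of 14 seed storage and late embryogenesis genes 7 rose and 1 fell at 8 days, 7 and 1 also adjusted over the list alone, and the list was not called (adjusted p = 0.0787). Those that rose were late embryogenesis and dehydrin genes such as OsPM19L1 (log2 4.50, or 5.32 without 8 day replicate 2), RAB16D and RAB16C. OsDhn1 fell (log2 -1.48), a call lost without 8 day replicate 2 (log2 -0.95). In growing callus several genes of this kind varied widely between replicates, EM standing at 31.9 ± 32.7 and RAB21 at 38.3 ± 47.9.

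Changes toward organ profiles were asked with sets defined in organ arrays alone. The 2814 leaf-biased probe sets had median log2 changes of 0.11 at 2 days, 0.15 at 4 days, 0.18 at 6 days and 0.26 at 8 days. All 4 shifts were called (adjusted p = 0.00125, 2.2e-05, 1.7e-08 and 2.8e-12), and those before 8 days were lost (adjusted p = 0.176, 0.119 and 0.0566 with an estimated correlation). The 8 day shift (415 rose, 26 fell) held at adjusted p = 0.027 with an estimated correlation. A member of either organ-biased set could pass the expression filter through its own organ's arrays alone. One that is low in growing callus can hardly fall, and how far this shaped the counts was not tested. The 2735 root-biased probe sets had a median of -0.10 at 2 days (adjusted p = 0.000208; adjusted p = 0.176 with an estimated correlation), of -0.18 at 4 days (adjusted p = 1.8e-06; adjusted p = 0.119 with an estimated correlation), of 0.03 at 6 days (adjusted p = 0.888) and of -0.02 at 8 days, where 303 rose and 314 fell (adjusted p = 0.889). Without 6 day replicate 3 the 6 day shift of the root-biased set was called (0.0468). Per day both sets had a median of 0.02 (adjusted p = 3.0e-07 for leaf and 3.9e-05 for root; adjusted p = 0.0669 and 0.173 with an estimated correlation).

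Across 2 to 8 days 6 of 11 photosystem and 11 of 24 aquaporin genes rose, while 4 of 29 DNA replication and 9 of 41 mitosis genes fell. All 4 lists were called, the latter 2 only at the preset correlation (adjusted p = 0.28 and adjusted p = 0.3 with an estimated correlation). CAB2R (LOC4324599) went from 0.157 ± 0.0192 at 2 days to 1.78 ± 0.469 at 8 days. Its linear contrast over the 4 times was 0.69 per day on the log2 scale, or 0.57 with the larger pseudocount. The rise was not steady, since its log2 change from growing callus was 3.8 at 6 days and 3.3 at 8 days. Os8N3 climbed back from 0.203 ± 0.123 to 2.08 ± 0.276. By the same contrast OsWOX9 (LOC4324824), the homeobox gene known from the root quiescent centre, fell by 0.32 per day. Its level was 2.86 ± 0.830 at 2 days and 0.855 ± 0.563 at 8 days.

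**Figure D2:**
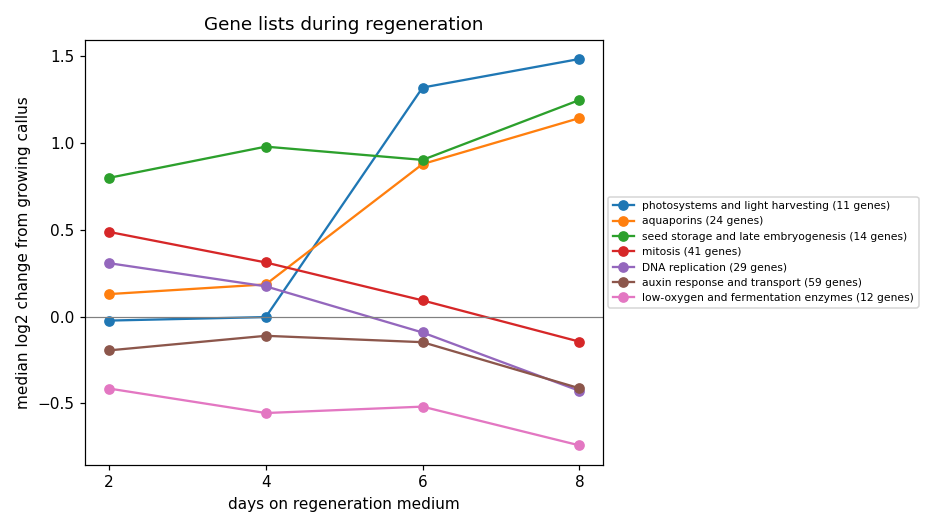
Median log2 change from growing callus (y axis) of 7 gene lists at 2, 4, 6 and 8 days on regeneration medium (x axis). The photosystem median lay at -0.02 at 2 days and 1.48 at 8 days, and the DNA replication median at 0.31 and -0.43.

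The change per day was called for 2162 probe sets, 1748 upward and 414 downward. OsMT-I-2b (log2 0.86 per day, SE 0.0609), the alpha-amylase gene AMY3A (LOC4347262, 0.73, SE 0.198, adjusted p = 0.0124), CAB2R, Os8N3 (0.63) and OsSAG12 (LOC4324982, 0.63), named for leaf senescence, were among the genes that rose. With the larger pseudocount OsMT-I-2b, CAB2R and Os8N3, whose mean levels at 2 days lay under the median of the arrays, gave 0.72, 0.57 and 0.52. AMY3A varied widely between replicates, at 28.3 ± 20.7 on 8 days, gave log2 0.85 per day without 8 day replicate 2 and lost its call without 8 day replicate 1 (log2 0.68 per day) or 3 (0.64) and without the arrays with excess poly(A) controls (0.64). IAA26 (LOC4347643, -0.36), the endoglucanase gene OsCel9C (LOC4338100, -0.35), OsCCR1 (-0.34), OsWOX9 and RASI (-0.30) were among those that fell. Of 11 photosystem genes 6 rose, 6 adjusted over the list alone, and of 24 aquaporin genes 11 rose, 11 adjusted over the list alone. Both lists were called (adjusted p = 1.0e-08 and 3.2e-07, and adjusted p = 0.0391 with an estimated correlation for each).

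Of 29 DNA replication genes 4 fell per day, 4 adjusted over the list alone (adjusted p = 2.0e-11; adjusted p = 0.28 with an estimated correlation). Among 41 mitosis genes 9 fell and 1 rose, the same adjusted over the list alone (adjusted p = 6.3e-07; adjusted p = 0.3 with an estimated correlation), with the kinesin genes KIN14A at log2 -0.20 per day and KIN4A at 0.22. Of 26 expansin genes 8 rose, 8 adjusted over the list alone (adjusted p = 0.00207, and adjusted p = 0.322 with an estimated correlation), and of 3 carbon fixation genes 2 rose, 2 adjusted over the list alone (adjusted p = 0.00525; adjusted p = 0.121 with an estimated correlation). Of 23 cytosolic ribosome genes 0 were called in limma and 0 adjusted over the list alone, with a median of -0.05 per day (adjusted p = 0.00133; adjusted p = 0.658 with an estimated correlation).

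Young leaf and root differed in the photosystem and low-oxygen lists, the lists of this comparison whose calls held with an estimated correlation (adjusted p = 0.0284 for both). PETE stood at 145 ± 10.8 in leaf (n = 4) and 0.249 ± 0.00918 in root (n = 3), and CAB2R at 134 ± 22.8 and 0.232 ± 0.00929. Adh2 (LOC4350054) stood at 146 ± 11.3 in root and 0.205 ± 0.0504 in leaf, and the pyruvate decarboxylase gene PDC1 (LOC4339066) at 138 ± 20.1 and 0.210 ± 0.0630. The silicon transporter gene Lsi2 stood at 33.9 ± 8.85 in root and 0.275 ± 0.131 in leaf.

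Leaf and root differed in 11931 probe sets, 5764 higher in leaf and 6167 lower. Higher in leaf were PETE (log2 9.37), CAB2R (9.33), the light-induced LIR1 (LOC4326442, 8.88), the chlorophyll-binding RCABP69 (LOC4343583, 8.77) and the aquaporin OsPIP2;7 (LOC4347729, 8.74). Lower were Adh2 (-9.42), PDC1 (-9.32), the protein kinase gene CPDK2 (LOC4333181, -8.69), ML (-8.62) and OsMT-I-4c (LOC4352582, -8.52). With the larger pseudocount PETE, CAB2R, RCABP69 and OsPIP2;7 gave 8.77, 8.69, 7.89 and 8.09, and Adh2, PDC1 and ML -8.81, -8.72 and -7.85, so the order of such values carries no information. All 11 photosystem genes were higher in leaf, 11 adjusted over the list alone (adjusted p = 6.5e-09), and 7 of 12 low-oxygen genes lower with 1 higher, the same adjusted over the list alone (adjusted p = 0.00133).

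Of 3 carbon fixation genes 3 were higher in leaf, 3 adjusted over the list alone (adjusted p = 0.00239, and adjusted p = 0.0608 with an estimated correlation). Of 16 chlorophyll synthesis genes 12 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 8.3e-06; adjusted p = 0.0608 with an estimated correlation), with CHLP at log2 6.76 (5.89 with the larger pseudocount) and PORB at 6.17. Of 44 secondary wall genes 32 were lower and 3 higher, the same adjusted over the list alone (adjusted p = 1.3e-05; adjusted p = 0.227 with an estimated correlation), with OsCCR1 at -7.60 and OsCAD3 at 6.17 (5.54 with the larger pseudocount). Of 41 mitosis genes 26 were lower and 2 higher, the same adjusted over the list alone (adjusted p = 3.9e-05, and adjusted p = 0.263 with an estimated correlation). Of 26 expansin genes 18 were lower, 18 adjusted over the list alone (adjusted p = 0.000232; adjusted p = 0.182 with an estimated correlation). Starch genes were higher in 6 of 15 and lower in 1, the same adjusted over the list alone (adjusted p = 0.0147; adjusted p = 0.182 with an estimated correlation), among them the synthase SS1 (log2 2.95). Clock genes were higher in 6 of 7 and lower in 1, OsCCA1 (log2 -2.04), the same adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.182 with an estimated correlation). Of 6 root markers 4 were lower in leaf, 5 adjusted over the list alone, and the list was not called (adjusted p = 0.0545). OsIRT1 among them (log2 -1.0, adjusted p = 0.0399) lost its call in many alternatives, as without root replicate 2 (log2 -0.47).

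Higher in shoot than root were most organ patterning (28 of 44), mitosis (26 of 41) and photosystem (10 of 11) genes, list calls that were lost (adjusted p = 0.145, 0.247 and 0.145 with an estimated correlation). The meristem gene OSH1 stood at 6.69 ± 0.970 in shoot and 0.170 ± 0.0809 in root (n = 3 each), and OsYAB2 at 5.92 ± 0.774 and 0.151 ± 0.0407. The copper transporter gene OsCOPT2 stood at 0.132 ± 0.0331 in shoot and 36.8 ± 7.50 in root. In all 10773 probe sets were called, 5751 higher in shoot and 5022 lower, a share of 53.4% higher that became 41.8% with the values as deposited, where the median of all probe sets shifted by -0.23. CAB2R (log2 8.82), the apyrase gene OsAPY3 (LOC4351367, 8.13) and the lipid transfer protein gene LTP2-B (LOC4351317, 7.58) were higher, and OsMT-I-4c (-8.62), CPDK2 (-8.34) and OsMT-I-1b (LOC4332487, -8.30) lower. With the larger pseudocount CAB2R, LTP2-B and OsMT-I-1b gave 8.19, 6.70 and -7.53.

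Of 44 organ patterning regulators 28 were higher in shoot and 3 lower, the same adjusted over the list alone (adjusted p = 3.25e-05; adjusted p = 0.145 with an estimated correlation). Of 41 mitosis genes 26 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 2.0e-05; adjusted p = 0.247 with an estimated correlation), and of 29 DNA replication genes 14 were higher, 14 adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.544 with an estimated correlation). Of 11 photosystem genes 10 were higher, 10 adjusted over the list alone (adjusted p = 3.25e-05; adjusted p = 0.145 with an estimated correlation). Of 83 mineral transport genes 34 were lower and 13 higher, the same adjusted over the list alone (adjusted p = 0.00167; adjusted p = 0.145 with an estimated correlation). Of 6 root markers 4 were lower, 5 adjusted over the list alone (adjusted p = 0.00565, and adjusted p = 0.147 with an estimated correlation). Of 30 heat shock genes 12 were lower and 3 higher, the same adjusted over the list alone (adjusted p = 0.00494; adjusted p = 0.292 with an estimated correlation). Of 23 pathogenesis-related genes 14 were lower and 4 higher, the same adjusted over the list alone (adjusted p = 0.00754; adjusted p = 0.422 with an estimated correlation).

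Of 16 chlorophyll synthesis genes 10 were higher in shoot than root and 1 lower, the same adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.191 with an estimated correlation). Of 23 cytosolic ribosome genes 6 were higher, 6 adjusted over the list alone (adjusted p = 0.00249; adjusted p = 0.647 with an estimated correlation), and of 15 starch genes 7 were higher, 7 adjusted over the list alone (adjusted p = 0.0127; adjusted p = 0.191 with an estimated correlation). Of 15 labdane diterpenoid genes 6 were lower, 5 adjusted over the list alone (adjusted p = 0.0395, and adjusted p = 0.447 with an estimated correlation), a call lost with the filter at the 75th percentile (0.183). Of 12 low-oxygen genes 5 were lower and 3 higher, the same adjusted over the list alone (adjusted p = 0.0454; adjusted p = 0.188 with an estimated correlation), a call lost in several alternatives, as without root replicate 1 (0.0600).

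Higher in shoot than young leaf were 35 of 41 mitosis and 19 of 26 expansin genes, and lower 10 of 11 photosystem and 6 of 7 clock genes. These list calls were lost (adjusted p = 0.123 for photosystems and 0.142 for the others with an estimated correlation). The expansin gene OsEXP7 (LOC4334606) stood at 14.7 ± 4.42 in shoot (n = 3) and 0.158 ± 0.00608 in leaf (n = 4), and the sucrose synthase gene OsSUS1 (LOC4333062) at 48.3 ± 11.9 and 0.475 ± 0.0331. The mitotic kinase gene CDC2Os-3 stood at 8.93 ± 1.44 and 0.265 ± 0.0130. The clock gene OsPCL1 (LOC4326391) stood at 0.151 ± 0.0368 in shoot and 38.6 ± 8.52 in leaf. Organ and growth place cannot be told apart here, since leaf came from a greenhouse and shoot from a chamber.

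**Figure D3:**
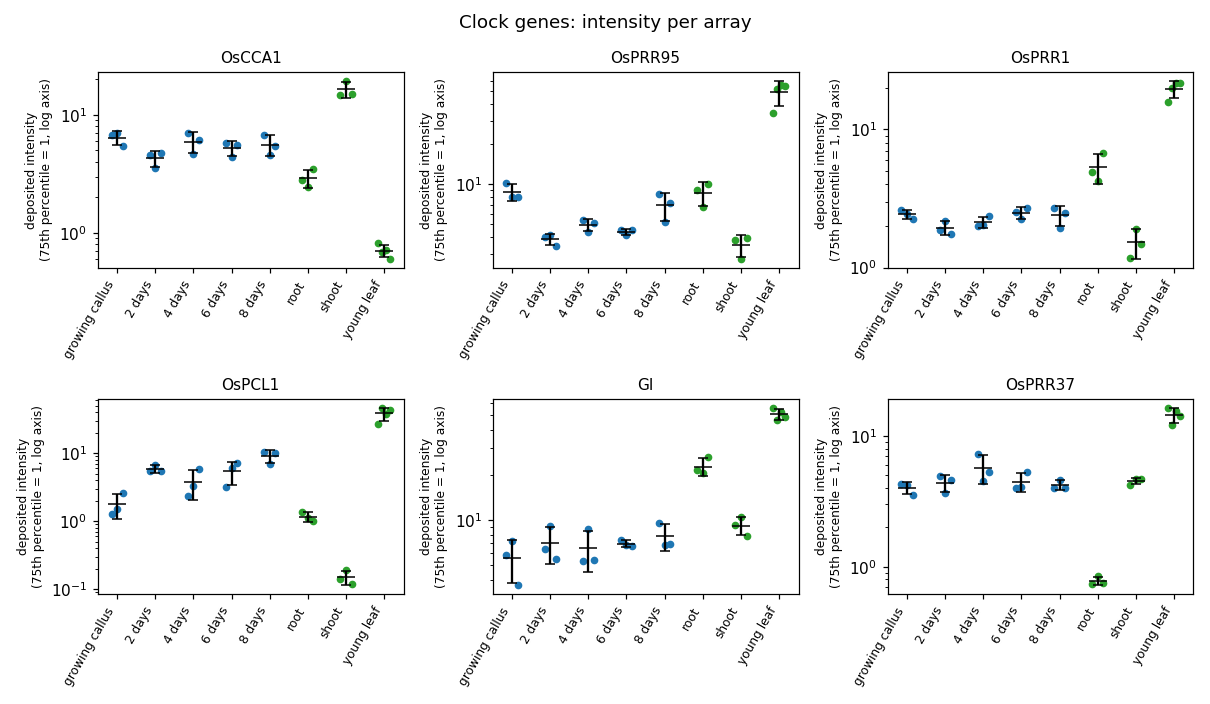
Deposited intensity (log axis, 75th percentile of an array equal to 1) of 6 clock genes in each array by group, with means as dashes and SD bars. OsCCA1 stood at 16.4 in shoot and 0.704 in young leaf, while OsPCL1 stood at 0.151 and 38.6.

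Shoot and leaf differed in 11713 probe sets, 6139 higher in shoot and 5574 lower, a share of 52.4% higher that became 47.6% with the values as deposited, where the median of all probe sets shifted by -0.17. By adjusted p alone it was 49.9%. LTP110-A (LOC4349601, log2 8.38), AP25 (LOC4331874, 6.90), OsSUS1 (6.75), the polygalacturonase inhibitor gene PGIP-1 (LOC4343645, 6.73) and OsEXP7 (6.49) were higher. OsPIP2;7 (-8.20), PDX12 (LOC4347937, -7.83), OsPCL1 (-7.50), OsBBD1 (LOC4326932, -7.35) and LIR1 (-7.33) were lower. With the larger pseudocount LTP110-A, PGIP-1, OsEXP7, PDX12 and OsPCL1 gave 7.50, 6.07, 5.79, -7.07 and -6.85, OsMCM5 3.38 and OSH71 4.51. Among 41 mitosis genes 35 were higher in shoot and 2 lower, the same adjusted over the list alone (adjusted p = 3.1e-09; adjusted p = 0.142 with an estimated correlation). Of 29 DNA replication genes 16 were higher, 16 adjusted over the list alone (adjusted p = 0.000104, and adjusted p = 0.444 with an estimated correlation), with OsMCM5 at log2 4.23. Of 44 patterning regulators 28 were higher and 1 lower, the same adjusted over the list alone (adjusted p = 3.7e-06; adjusted p = 0.123 with an estimated correlation), with OSH71 at 5.22. Of 26 expansin genes 19 were higher, 19 adjusted over the list alone (adjusted p = 0.000104; adjusted p = 0.142 with an estimated correlation), and of 59 auxin genes 27 were higher and 5 lower, the same adjusted over the list alone (adjusted p = 0.00121, and adjusted p = 0.142 with an estimated correlation).

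Lower in shoot were 10 of 11 photosystem genes, 10 adjusted over the list alone (adjusted p = 1.7e-05; adjusted p = 0.123 with an estimated correlation), with LFNR1 at log2 -6.58. Of 15 labdane diterpenoid genes 13 were lower, 13 adjusted over the list alone (adjusted p = 0.000493; adjusted p = 0.142 with an estimated correlation), with the copalyl diphosphate synthase gene OsCPS2 at -4.56 (-3.73 with the larger pseudocount). Of 7 clock genes 6 were lower and OsCCA1 was higher (log2 4.60), the same adjusted over the list alone (adjusted p = 0.00824, and adjusted p = 0.142 with an estimated correlation). Of 3 carbon fixation genes 3 were lower, 3 adjusted over the list alone (adjusted p = 0.00342; adjusted p = 0.123 with an estimated correlation), and of 16 chlorophyll synthesis genes 11 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.00342; adjusted p = 0.193 with an estimated correlation). Of 83 mineral transport genes 25 were lower and 14 higher, the same adjusted over the list alone (adjusted p = 0.0298, and adjusted p = 0.194 with an estimated correlation). Higher were 19 of 23 cytosolic ribosome genes with 2 lower (adjusted p = 0.00124; adjusted p = 0.647 with an estimated correlation) and 25 of 44 secondary wall genes with 2 lower (adjusted p = 0.00342; adjusted p = 0.457 with an estimated correlation), the same counts adjusted over the list alone.

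Among the named genes that differed between growing callus and the organs were alpha-amylase, hemoglobin and jasmonate repressor genes. The alpha-amylase genes AMY3E (LOC4345812) and AMY1A (LOC4330832) stood at 55.8 ± 39.3 and 22.9 ± 9.96 in callus, against 0.158 ± 0.0193 and 0.0898 ± 0.0276 in root, the organ with the highest mean for both. NSHB1 (LOC4332166) stood at 95.6 ± 6.12 in callus and 1.81 ± 0.266 in root. The jasmonate repressor gene OsJAZ13 (LOC4348531) stood at 0.159 ± 0.0111 in callus and between 28.2 ± 2.04 in root and 55.1 ± 16.4 in leaf.

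Against the mean of the organs, 4977 probe sets were higher in callus and 5064 lower, of which 4292 (86.2%) and 3784 (74.7%) had that sign against each organ. By adjusted p alone the balance turned, with 11719 higher and 10874 lower. Named genes that differed included OsTDL1B (LOC9270335, log2 9.47), AMY3E (7.96), AMY1A (7.69), NSHB1 (7.46) and NSHB2 (LOC4332123, 7.42), and OsMT-I-2b (-9.50), OsJAZ13 (-7.72), BHLH148 (LOC4334060, -6.83), OsTIFY11a (LOC4331832, -6.62) and OsTIFY11b (LOC4331834, -5.64). Without growing callus replicate 3 the value of AMY3E was 8.83. With the larger pseudocount OsTDL1B, AMY3E and AMY1A gave 8.79, 7.19 and 6.59, and OsMT-I-2b, OsJAZ13 and OsTIFY11a -8.50, -7.04 and -6.01. Of 29 DNA replication genes 22 were higher, 22 adjusted over the list alone (adjusted p = 6.0e-08, and adjusted p = 0.278 with an estimated correlation). Of 23 cytosolic ribosome genes 15 were higher, 15 adjusted over the list alone (adjusted p = 0.000146; adjusted p = 0.418 with an estimated correlation). Of 12 low-oxygen genes 7 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.0245; adjusted p = 0.182 with an estimated correlation). Of 15 starch genes 7 were higher and 2 lower, the same adjusted over the list alone, and the list was not called (adjusted p = 0.391).

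Of 11 photosystem genes 10 were lower in callus, 10 adjusted over the list alone (adjusted p = 4.15e-07, and adjusted p = 0.145 with an estimated correlation). Of 35 jasmonate genes 18 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 3.8e-05; adjusted p = 0.278 with an estimated correlation), including the allene oxide synthase gene AOS1 (log2 -4.95). Of 24 aquaporin genes 15 were lower and 3 higher, the same adjusted over the list alone (adjusted p = 0.00202; adjusted p = 0.272 with an estimated correlation); OsPIP1;2 was at -3.78 and OsTIP3 at 6.82, or 7.80 without growing callus replicate 3 and 6.17 with the larger pseudocount. Of 44 secondary wall genes 23 were lower and 5 higher, the same adjusted over the list alone (adjusted p = 0.000429, and adjusted p = 0.37 with an estimated correlation), with BC1 at -2.98 and OsCAD7 at 3.92. Of 3 carbon fixation genes 3 were lower, 3 adjusted over the list alone (adjusted p = 0.00958; adjusted p = 0.182 with an estimated correlation), and of 16 chlorophyll synthesis genes 5 were lower, 5 adjusted over the list alone (adjusted p = 0.00396; adjusted p = 0.278 with an estimated correlation). Of 41 mitosis genes 19 were higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.00958, and adjusted p = 0.418 with an estimated correlation). Of 83 mineral transport genes 27 were lower and 13 higher, the same adjusted over the list alone (adjusted p = 0.0386; adjusted p = 0.278 with an estimated correlation), a call lost without growing callus replicate 3 (0.0590).

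The 4 callus times were each set against the same 3 growing callus arrays, which alone makes their changes resemble each other. Across probe sets the log2 changes at 2 and 8 days correlated at 0.604, and those at 6 and 8 days at 0.918, where simulated arrays without any change but with shared controls gave 0.499. The share of probe sets with the same sign at 2 and 8 days was 67.5% against 66.6% simulated, and at 6 and 8 days 82.5%. The covariance for 2 and 8 days was 0.178 against 0.0234 simulated. Called as higher at both 2 and 8 days were 403 probe sets, where independent lists give 31.1, and as lower 489, where they give 25.3, while 13 were called in opposite directions. The values for independent lists leave out the shared controls and are not what no change would give, and part of the excess may come from those controls. The 3 growing callus arrays are too few to be split between comparisons.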

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

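Chosen only after the result was seen were both tests of leaf tissue in the callus, the test of harvest time, the scale on which single arrays were compared within young leaf, and the stricter reading of the storage protein, RNA quality and both leaf tissue tests.

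Between 2 and 8 days the change from growing callus differed in 11 of 14 named genes tested, by limma on the difference itself. These genes were named for large changes at 2 or 8 days, which favours such differences, so their number says nothing about other genes. The difference, 8 days minus 2 days on the log2 scale, was 2.79 for Agglutinin (adjusted p = 0.00660), 3.30 for Os8N3 (1.3e-06), 1.68 for OsDhn1 (0.00127), 2.88 for RAB16D (0.0227), 4.60 for OsMT-I-2b (5.3e-08), 3.52 for RAB16C (0.0324), 2.91 for PETE (9.2e-08), -1.86 for OsCCR1 (5.1e-06), -1.77 for RASI (0.00143), -1.18 for Chib3H-a (0.0415) and -1.27 for IAA9 (0.00259). Os8N3 stood at -3.81 at 2 days and -0.51 at 8 days relative to growing callus, and OsDhn1 at -3.16 and -1.48. For RAB16D 8 day replicate 2 (1.52) lay under all 3 arrays at 2 days (1.74 to 2.20).

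Of 25 lists, 9 differed between 2 and 8 days. The median differences were 1.35 for photosystems (adjusted p = 9.1e-09; adjusted p = 0.0481 with an estimated correlation) and 0.93 for aquaporins (5.6e-07; 0.0481), both also called with an estimated correlation. The others were 1.40 for carbon fixation (0.00700; 0.129), -0.33 for cytosolic ribosome (0.000547; 0.627), -0.83 for DNA replication (7.6e-12; 0.259), -0.65 for mitosis (3.0e-07; 0.262), 0.44 for expansins (0.00725; 0.373), 0.34 for starch (0.0469; 0.296) and 0.43 for the clock (0.0486; 0.296), each lost with an estimated correlation (the latter p).

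In young leaf, the only group of 4 arrays, 6 of 100 named genes and 0 of 3 array measures had an array set apart, its gap to the nearest other array over the range of the group passing the critical value of Dixon's ratio for 4 values, which chance gives in about 1 in 20. The ratios were 0.857 for OsEXP7 (replicate 4) and, in replicate 1, 0.844 for OsTDL1B, 0.858 for OsPRR95, 0.839 for OsIRT1, 0.921 for OsMCM3 and 0.842 for OsORC3. This used the log2 of deposited values. In the arrays set apart, OsEXP7, OsTDL1B, OsIRT1, OsMCM3 and OsORC3 lay at 0.149, 0.283, 0.246, 0.249 and 0.135, under the array median. OsPRR95 stood at 34.0. Replicate 1 had the highest median of the 4 arrays, 0.3296 against 0.2567 to 0.2825. An earlier run on quantile-normalized values gave 4 genes, of which only OsTDL1B was shared.

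Outside the compared probe sets, the 36 poly(A) control probe sets averaged 238 to 244 in the 3 arrays that the labels describe as carrying an excess and 0.271 to 1.94 in the other 22, a ratio of 122 between the lowest and the highest of these.

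Of 9 late embryogenesis, RAB16 and oil body genes 7 rose at 8 days, OsDhn1 fell and PXG was not called, with a median log2 change of 3.49, and the list that holds them was not called (adjusted p = 0.0787). Quantile normalization is argued against by a median of 3.43 with the values as deposited. A scaling before deposit was not tested. Seed tissue carried over in the callus stays open: the 10 storage protein genes had a median log2 change of -0.052, but 5 of them did not pass the expression filter, the levels at 8 days were 0.0668 to 0.666, and no seed array gives the level to be looked for. RNA quality of the 8 day arrays stays open, since only 1 of the 3 arrays had a 3' to 5' ratio of control transcripts within the range of growing callus (2.17 within 1.95 to 2.20), the other 2 lay below it at 1.69 and 1.93, and the bound first written, 1 array within the range, would have excluded it and was set aside as too lenient after the values were seen. The days on regeneration medium remain an untested biological explanation.

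Leaf-biased transcripts were higher at 8 days. Quantile normalization is argued against by the shift of the leaf-biased set relative to all probe sets, 0.32 with the values as deposited and 0.30 after it. A scaling before deposit was not tested. Mature leaf tissue mixed into the callus stays open, since no mature leaf was measured and young leaf stood in for it. Equal shares were tested first: over 99 of the 100 most abundant leaf-biased probe sets, those higher in young leaf than in growing callus, the lower quartile of the share of leaf RNA needed was 0.0815 of the upper, under a bound of 0.1, but with a bootstrap interval of -0.276 to 0.218 that test did not decide. A further test, added because that margin was narrow, counted probe sets under 1 in growing callus, and in 11 of 49 every 8 day array lay under 50% of the rise that the median share of 1.36% needs. That count rests on the shares already seen and has no spread of its own, so it decides nothing either. Development of leaf-like gene expression with time on the medium may account for it, a hypothesis not tested here.

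Clock genes differed between shoot and young leaf, 6 lower and 1 higher in shoot. Quantile normalization is argued against, since 7 of 7 genes kept their call and sign with the values as deposited. A scaling before deposit was not tested. Harvest at different times of day stays open: 1 gene went the minority way, OsCCA1, at 16.4 ± 2.53 in shoot and 0.704 ± 0.0861 in leaf, but that was known before the test was written, so it decides nothing. The labels give no harvest times. Organ and growth place, which differ together, and plant stage stay open as well and were not tested.

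Other splits of the same arrays were counted for each comparison. With 10 splits of 3 against 3 arrays the splits are too few for a share under 0.05. The real split, the only 1 as large, called 1520 probe sets at 2 days (highest other 7), 1952 at 4 days (1), 2266 at 6 days (2), 2922 at 8 days (174) and 10773 for shoot against root (3). The share was under 0.05, with only the real split as large, for young leaf against root (11931, highest other 9395, of 35 splits), shoot against young leaf (11713, 8832, of 35), the change per day (2162, 1118, of 100) and growing callus against organs (10041, 8395, of 100). The 100 splits were the real one and others drawn at random, and shares this small do not exclude chance. The highest other splits of both leaf comparisons set 3 leaf arrays against all 3 arrays of the other organ plus 1 leaf array.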

How the results depend on the processing

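Recomputing the lists and organ sets under the alternatives first meant for the counts alone (all but the estimated correlation, the values as deposited, all probe sets of a list and the set thresholds), and treating the poly(A)-excess arrays as a block, were chosen after seeing the data; the other alternatives were planned. None of the 317 values of named genes, 82 list calls and 8 organ set calls changed direction (other called probe sets were counted, not followed), but the balance of calls did with the values as deposited: the share higher in shoot went from 53.4% to 41.8% against root and from 52.4% to 47.6% against leaf. Without the fold threshold the share higher turned at 2 days (40.4% to 51.2%), at 4 days (40.8% to 52.9%), for shoot against leaf (to 49.9%) and for callus against organs (49.6% to 51.9%). Without the fold threshold the counts rose to 4129 (2 days), 5530 (4 days), 5410 (6 days), 7943 (8 days), 7116 (per day), 22513 (leaf against root), 21490 (shoot against root), 21515 (shoot against leaf) and 22593 (callus against organs), by construction. With an estimated correlation 5 of 82 list calls and 1 of 8 organ set calls were left. All other counts stayed within 1.5 times. Leaving out 1 array at a time gave 1188 to 1632, 1570 to 2149, 2022 to 2404, 2640 to 3397, 1662 to 2880, 11784 to 12330, 10535 to 11407, 11523 to 12041 and 9851 to 10280 in the same order, 79 to 91 list calls and 8 to 9 organ sets. With the replicate number as a block the counts were 1511, 1950, 2277, 2930, 2169, 11902, 10777, 11710 and 10080. List calls then numbered 85 and organ sets 8. Outside the 4 day comparison the preset rule for pairing was not met, which does not exclude pairing there. A block shared by all groups does not test the pairing within the 4 day comparison. Without the poly(A)-excess arrays the callus counts were 1684, 2162, 2186, 2819 and 2013. With the values as deposited, the median of all probe sets shifted by -0.17 at 8 days, -0.19 for leaf against root, -0.23 for shoot against root and -0.17 for shoot against leaf (0.05 for shoot against root when quantile normalized), and list calls numbered 96. With the stricter filter the medians were -0.10 for leaf against root and 0.20 for shoot against root. Across settings, named genes kept their side of the threshold in 11931 values, with 55 weaker and 55 stronger, and list tests in 3008, with 108 weaker. Of the alternatives behind these changes, none tests a cause.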

Other observations

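No test was chosen for this part after results were seen; its values come from the planned fit. Class III peroxidase and glutathione S-transferase lists were called in no comparison. Of 3 peroxidase genes 0 were called at 2 days, with a median log2 of -0.01 and a mean of -0.31 (adjusted p = 0.844), and of 6 glutathione S-transferase genes 2 fell (adjusted p = 0.366). At 8 days 1 peroxidase gene rose and the list had a median of -0.21 and a mean of 0.23, with the test pointing up (adjusted p = 0.978). For the transferases at 8 days 2 fell and 1 rose, with a median of 0.43 and a mean of -0.08 (adjusted p = 0.533).

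The homeobox gene OsWOX11 stood higher in growing callus than in the organs (log2 3.16). The iron chelator synthesis genes OsNAS1 (log2 2.66, adjusted p = 0.0379) and OsNAS2 (log2 2.23, adjusted p = 0.0214) rose at 6 days, at intensities of 1.82 ± 1.65 and 1.83 ± 1.48. Probe sets of the same gene gave opposite calls for CHLH, OsHSF6, OsPIP2;1, PAL and PRX112 in at least 1 comparison.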
